A study of Mus musculus with 6 samples.

How the data were processed

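Intestinal crypts were collected from C57BL/6 mice, 2 libraries each without irradiation (Control), 3 days after abdominal irradiation (AIR), and 3 days after abdominal irradiation with MPLA (AIR + MPLA). Per the labels' protocols, crypts were frozen, RNA was taken up in Trizol, and libraries were made with the TruSeq RNA kit of Illumina. Per the submitters' processing notes, the tools were Trimmomatic, HISAT2, Cufflinks and HTSeq on GRCm38.p6; their versions, their order and the strand setting of the counting are not given in the sources used here, so a gene and an antisense partner cannot be told apart. The deposited values were FPKM per gene, in 1 file per sample and in 1 table of the series. The columns headed as counts in the files of single samples also held FPKM: in 5 of the 6 files all 21878 values equalled the series table within 1e-06. Control replicate 2 was the exception, with no value above 0 shared between its own file and its column of the series table (FPKM totals 381669 and 503961). Columns of the series table were matched to samples by name. Of the 21878 genes 21727 had their ID in a RefSeq gene table of GRCm38.p6, which gave the coordinates, and 20226 had a transcript GC content from GENCODE transcripts of that build; 27 symbols turned into dates in the files were restored by gene ID.

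Groups and replicate numbers came from the sample titles. The planned test was for read counts; as the values are FPKM, the fall-back named in the plan was used. Genes with at least 1 FPKM in at least 2 of the 6 libraries were kept (10415). On log2(FPKM + 1), limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all 6 libraries (3 residual degrees of freedom) with a mean-variance trend and robust empirical Bayes, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. No further scaling was applied to FPKM. The depth in reads is unknown, so no counting interval is given. Relative depth was estimated from the most common ratio of the values of low genes, those up to 0.1 FPKM, to Control replicate 3, at which 12.5% to 21.5% of the ratios lay. Tables and figures used Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

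Gene lists, the test design, the rule for named genes and a set of other settings were fixed before the data were examined. There were 35 lists with 829 entries, 806 of them in the files. The 29 lists with at least 3 tested members were tested with camera (limma) at a preset correlation of 0.01, two-sided and adjusted over the 29. Camera with an estimated correlation and fry were alternatives. With an estimated correlation camera has only the 3 residual degrees of freedom, so its larger p-values do not measure the correlation of members alone. The lists of B and plasma cells, neutrophils, fibroblasts and smooth muscle, enteric glia and neurons, and erythrocytes had fewer than 3 tested members and the list of mitochondrially encoded genes had none in the files, so they were not analysed here. The median, the mean and the test of a list differed in sign for 4 lists in AIR against Control, 5 in AIR + MPLA against AIR and 2 in AIR + MPLA against Control, none of them called. Gene Ontology and pathway terms that the deposited files attach to genes, of 10 to 300 tested members (2681), were tested by camera at the preset correlation.

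By the rule, the text named 10 genes in every comparison whether or not they passed (Lgr5, Olfm4, Cdkn1a, Mki67, Clu, Lyz1, Muc2, Tlr4, Isg15 and Tnf). It added the 5 largest rises and 5 largest falls (3 each for AIR + MPLA against Control) among genes past the threshold, without predicted genes, with no overlap of the libraries and a mean of at least 5 FPKM in the higher group. It added for each list with at least 3 called members the 2 with the smallest p in the main direction and the 1 the other way, of which the text leaves many out. All are counted among the named genes, including 1 that is not reported here. The rule set the 5 in CPM, which became FPKM here.

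Other settings fixed beforehand were median-ratio (RLE) and upper-quartile scaling, totals without haemoglobin and defensin genes, no filter, a pseudocount of 0.1, only the 4 libraries compared, each library left out in turn, and the replicate number as a block on the 4 irradiated libraries. Chosen after seeing the data were the series-table values of Control replicate 2, a correction for GC content (a lowess trend with span 0.3 of each library's deviation from the gene mean), both together, GC and length correction, the block with GC correction, a filter of 5 FPKM, and a split of the AIR libraries that set 1 against Control and the other against AIR + MPLA. GC content was known for 96.6% of tested genes. A library left alone in its group was taken to vary like the other groups.

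The steps were tested on simulated data of 10415 genes, 200 of them changed. For AIR against Control without a GC trend in the simulated data, 78% of 2-fold and 97% of 4-fold changes were recovered with 12 unchanged genes called. With the observed GC trend and no correction, as in the main values, 49% and 97% were recovered with 36 unchanged genes called. For AIR + MPLA against AIR with the observed GC trend in the simulated data, 493 unchanged genes were called without correction and 9 with it. For AIR against Control, camera called 20 of 20 shifted lists and 0 of 600 unshifted ones. The simulated genes varied independently of each other, so this does not show how often camera calls unshifted lists whose members vary together. The estimated correlation of members was 0.118 for p53 targets and 0.906 for Paneth cell genes. The simulated correlation of the comparisons that share the AIR libraries came from 100 draws with no difference between AIR + MPLA and AIR and with noise independent between genes.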

Results

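RNA was sequenced from intestinal crypts of C57BL/6 mice in 3 groups of 2 libraries each. Control crypts came from mice without abdominal irradiation and AIR crypts from mice 3 days after it. AIR + MPLA crypts came from mice irradiated likewise and given MPLA, a lipid A derivative that activates Toll-like receptor 4. The libraries were replicates 2 and 3 of Control and replicates 1 and 3 of both irradiated groups. Nothing in the labels says that replicates came from separate mice, so the p-values measure the spread between these samples, which may be technical. Values were FPKM for 21878 genes, and the number of reads behind them is unknown. FPKM totals were 381669 and 492247 in Control replicates 2 and 3, 398242 and 419566 in AIR replicates 1 and 3, and 441942 and 454781 in AIR + MPLA replicates 1 and 3. Between 9842 and 10179 genes reached 1 FPKM in each library. From the value of 1 read in low genes, depth relative to Control replicate 3 was estimated. It was 0.95 in Control replicate 2, 0.86 and 0.74 in AIR replicates 1 and 3, and 0.95 and 0.84 in AIR + MPLA replicates 1 and 3.

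The first principal component held 56.7% of the variance of log2(FPKM + 1). It set the AIR libraries (scores 40.7 and 37.3) apart from AIR + MPLA (-15.3 and -18.6) and Control (-10.0 for replicate 2 and -34.1 for replicate 3). Across genes, which are not independent replicates, Pearson's r was 0.972 between the Control libraries, 0.982 between the AIR libraries and 0.994 between the AIR + MPLA libraries. Control replicate 2 has other values in its own file than in the column of the series table that carries its name. Its own file was used, and results with the series-table values are given for the genes and lists of the text that then lie on the other side of the threshold. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Coordinates are of GRCm38.p6.

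AIR was compared with Control to find which crypt transcripts differed 3 days after abdominal irradiation. Stem cell transcripts fell: 18 of 21 tested markers of crypt base columnar cells were lower in AIR, and the other 3 did not pass the test. Lgr5, the R-spondin receptor that marks these cells (gene ID 14160, chromosome 10, 115450314 to 115587780), was at 0.267 ± 0.00240 FPKM in AIR and 3.89 ± 0.470 in Control (SD, n = 2; log2 fold -1.95, SE 0.18, limma adjusted p = 0.00453). Transcripts of regenerative and fetal-like epithelium rose in 10 of 20 tested members, and the other 10 did not pass. Ly6a, whose product Sca-1 marks repairing epithelium (gene ID 110454, chromosome 15, 74994877 to 74998031), was at 114 ± 73.4 FPKM in AIR and 2.96 ± 1.51 in Control (SD, n = 2; log2 fold 4.76, SE 0.55, limma adjusted p = 0.00547).

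When adjusted over the list alone, 19 stem cell markers were lower. The list had a median log2 fold of -1.17 (camera adjusted p = 5.63e-08; adjusted p = 0.549 with an estimated correlation). Olfm4, another stem cell transcript (gene ID 380924, chromosome 14, 80000302 to 80023141), fell from 633 ± 128 to 168 ± 109 FPKM (SD, n = 2; log2 fold -2.06, SE 0.46, limma adjusted p = 0.0212). Axin2, a Wnt target, fell from 14.8 ± 2.02 to 3.60 ± 0.926 FPKM (log2 fold -1.78, limma adjusted p = 0.00546). Of the regenerative transcripts 13 were higher when adjusted over the list alone. Over the regenerative list the median log2 fold was 1.39 (camera adjusted p = 5.63e-08; adjusted p = 0.549 with an estimated correlation). S100a6, a calcium-binding protein, rose from 18.1 ± 5.90 to 332 ± 172 FPKM (SD, n = 2; log2 fold 4.05, SE 0.39, limma adjusted p = 0.00453). Clu, a marker of revival stem cells, was at 5.30 ± 4.65 FPKM in AIR and 0.0930 ± 0.0382 in Control (log2 fold 2.30, limma adjusted p = 0.0183). Its SD in AIR was close to its mean. Other large rises were those of Nt5e, the ecto-5'-nucleotidase CD73 (log2 fold 4.29, limma adjusted p = 0.00732), and Anxa10, an annexin (log2 fold 3.71, limma adjusted p = 0.00626). Ly6d rose as well (log2 fold 3.68, limma adjusted p = 0.00945). Among EGF receptor ligands 3 of 4 tested members rose, or 3 rose and 1 fell when adjusted over the list alone. They included Areg, which encodes amphiregulin (log2 fold 2.57, limma adjusted p = 0.0149), and Btc, which encodes betacellulin (log2 fold 1.39, limma adjusted p = 0.0125). The list as a whole did not pass (camera adjusted p = 0.0578).

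Targets of p53 rose and cell cycle transcripts fell. Of 30 tested p53 targets 14 were higher and 1 lower, or 16 and 1 when adjusted over the list alone. Over the p53 targets the median log2 fold was 0.49 (camera adjusted p = 4.83e-07; adjusted p = 0.549 with an estimated correlation). Ccng1, which encodes cyclin G1 (gene ID 12450, chromosome 11, 40748552 to 40755309), was at 67.4 ± 2.38 FPKM in AIR and 18.3 ± 6.25 in Control (SD, n = 2; log2 fold 1.87, SE 0.24, limma adjusted p = 0.00681). Phlda3, a p53-induced inhibitor of Akt, was at 6.91 ± 3.67 FPKM and 0.326 ± 0.294 (log2 fold 2.51, limma adjusted p = 0.00784). The member that fell was Sesn1, a stress-response gene (log2 fold -0.49, SE 0.14, limma adjusted p = 0.0429; after removal of the trend with GC content log2 fold -0.28, SE 0.12, adjusted p = 0.127). Cdkn1a, which encodes the cell cycle inhibitor p21, did not pass, at 82.0 ± 29.2 FPKM in AIR and 52.2 ± 23.0 in Control (log2 fold 0.67, limma adjusted p = 0.198). DNA replication genes fell in 21 of 40 tested members, 27 when adjusted over the list alone. Over the replication genes the median log2 fold was -0.75 (camera adjusted p = 1.10e-06; adjusted p = 0.549 with an estimated correlation). Mcm2, a subunit of the replicative helicase, fell from 22.4 ± 2.12 to 8.17 ± 0.114 FPKM (SD, n = 2; log2 fold -1.35, SE 0.14, limma adjusted p = 0.00538). Lig1, DNA ligase 1, fell likewise (log2 fold -1.27, limma adjusted p = 0.00546). Mitosis genes fell in 18 of 40, 21 when adjusted over the list alone. Over the mitosis genes the median log2 fold was -0.52 (camera adjusted p = 0.000141; adjusted p = 0.549 with an estimated correlation). Aurkb, the Aurora B kinase, was among those that fell (log2 fold -1.22, limma adjusted p = 0.00734). Mki67, the Ki-67 gene, did not pass (log2 fold -0.50, limma adjusted p = 0.350; log2 fold 0.12 with the series-table values of Control replicate 2). Its Control libraries had an SD of 14.8 around a mean of 24.1 FPKM.

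Type I interferon response genes rose in 17 of 30 tested members, 24 when adjusted over the list alone. Over the type I interferon genes the median log2 fold was 1.31 (camera adjusted p = 7.44e-12; adjusted p = 0.549 with an estimated correlation). Ifit1, an antiviral RNA-binding protein, was at 56.1 ± 32.1 FPKM in AIR and 4.95 ± 0.988 in Control (SD, n = 2; log2 fold 3.15, SE 0.46, limma adjusted p = 0.00890). Rtp4, another member, rose too (log2 fold 2.38, limma adjusted p = 0.00813). Isg15, a ubiquitin-like modifier, was at 121 ± 75.8 FPKM and 21.8 ± 16.4 (log2 fold 2.48, limma adjusted p = 0.0383). It did not pass with the series-table values of Control replicate 2 (log2 fold 1.51, limma adjusted p = 0.0768). Genes of interferon gamma response and antigen presentation went both ways. Of 26 tested, 2 were higher and 11 lower, as many when adjusted over the list alone (camera adjusted p = 0.331). The 2 smallest p-values among the members that fell belonged to MHC class II genes. Cd74, the invariant chain (gene ID 16149, chromosome 18, 60803849 to 60812652), fell from 171 ± 71.0 to 17.1 ± 2.44 FPKM (SD, n = 2; log2 fold -3.19, SE 0.28, limma adjusted p = 0.00453). H2-Eb1, a class II beta chain, fell too (log2 fold -2.60, limma adjusted p = 0.00453). Gbp7, a guanylate-binding protein, rose (log2 fold 1.10, limma adjusted p = 0.0140). Tlr4 itself stayed below the filter and was not tested. It was at 0.017 and 0.012 FPKM in the Control libraries, 0.240 and 0.123 in AIR, and 0.0062 and 0.015 in AIR + MPLA. Tnf, which encodes tumour necrosis factor, did not pass (log2 fold 0.07, limma adjusted p = 0.850; log2 fold -0.26 with the series-table values).

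Markers of several differentiated and immune cells fell. Paneth cell genes were lower in 14 of 24 tested members, 18 when adjusted over the list alone. Over the Paneth cell genes the median log2 fold was -1.92 (camera adjusted p = 4.88e-05; adjusted p = 0.684 with an estimated correlation). The list passed camera without each library, but the median was -0.9996 without Control replicate 3, -2.60 without Control replicate 2 and -2.86 with the series-table values of Control replicate 2. Lyz1, Paneth cell lysozyme, was at 1448 ± 152 FPKM in AIR and 5985 ± 4376 in Control (SD, n = 2; log2 fold -1.83, SE 0.50, limma adjusted p = 0.0384). After GC correction its fold was nearly the same but it missed the limma threshold (log2 fold -1.71, SE 0.53, adjusted p = 0.0563). With the series-table values of Control replicate 2 as well, it passed (log2 fold -2.73, limma adjusted p = 0.000340). Defensins took 5.90% and 12.7% of all FPKM in Control replicates 2 and 3 but 2.25% and 2.39% in the AIR libraries. Defa26, an antimicrobial alpha-defensin, fell by 3.02 on the log2 scale (limma adjusted p = 0.00989), and Defa29, another, by 2.96 (limma adjusted p = 0.0101). Defensins, Ly6, H2 and Gst genes are paralog families whose reads can be split among near-identical copies, so their single-gene values are uncertain. Tuft cell markers fell in 10 of 12, all 12 when adjusted over the list alone. Over the tuft cell markers the median log2 fold was -1.12 (camera adjusted p = 1.64e-06; adjusted p = 0.365 with an estimated correlation). They included Alox5ap, needed for leukotriene synthesis (0.542 ± 0.00569 FPKM in AIR against 5.65 ± 1.27; log2 fold -2.10, SE 0.18, limma adjusted p = 0.00453). T cell and intraepithelial lymphocyte markers fell in 10 of 11, as many when adjusted over the list alone. Over the T cell markers the median log2 fold was -1.28 (camera adjusted p = 1.53e-05; adjusted p = 0.549 with an estimated correlation). Examples were the chemokine gene Ccl5 (log2 fold -2.24, limma adjusted p = 0.00733) and Nkg7, of cytotoxic granules (log2 fold -1.86, limma adjusted p = 0.00755). Notch signalling genes were lower in 6 and higher in 1 of 12, or 8 and 1 when adjusted over the list alone (camera adjusted p = 0.0174; adjusted p = 0.549 with an estimated correlation). Hes1, a Notch target, was lower (log2 fold -1.34, limma adjusted p = 0.00755) and the ligand gene Jag2 higher (log2 fold 0.71, limma adjusted p = 0.0288).

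**Figure D1:**
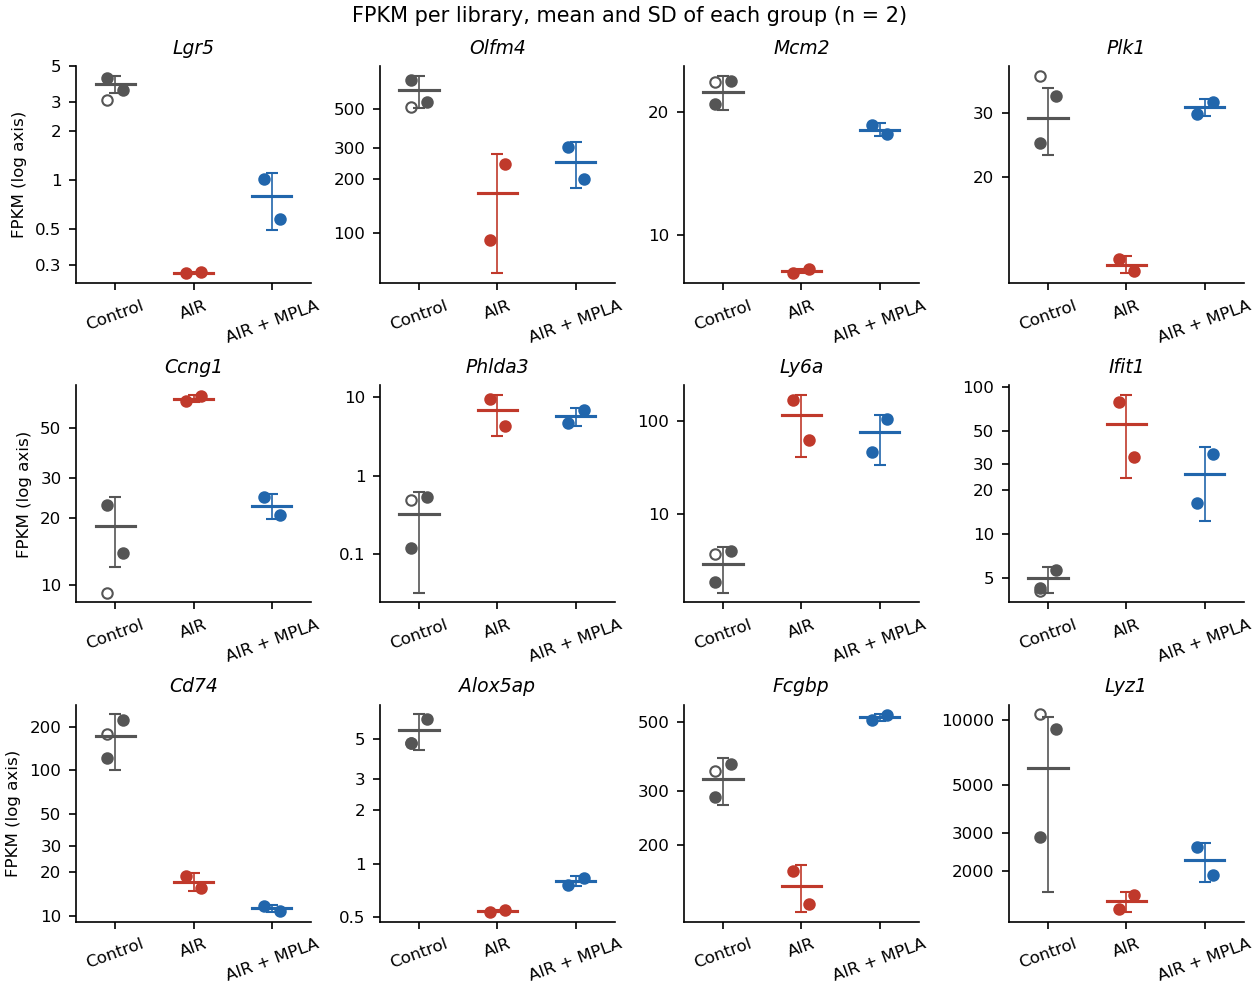
FPKM of 12 genes in each library on log axes, with Control in grey, AIR in red and AIR + MPLA in blue; lines are group means, bars 1 SD (n = 2), and open circles the series-table value of Control replicate 2, which is in no mean. Lgr5 lay at 0.267 FPKM in AIR against 3.89 in Control and 0.791 in AIR + MPLA, and Ccng1 at 67.4, 18.3 and 22.6.

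Absorptive enterocyte genes moved both ways, 7 higher and 4 lower of 30, or 8 and 4 when adjusted over the list alone. Over the enterocyte genes the median log2 fold was 0.35 (camera adjusted p = 0.0175; adjusted p = 0.684 with an estimated correlation). Fabp2, the intestinal fatty acid-binding protein, rose from 841 ± 197 to 2308 ± 74.9 FPKM (SD, n = 2; log2 fold 1.48, SE 0.24, limma adjusted p = 0.0103). Lct, lactase, fell from 31.8 ± 6.45 to 2.87 ± 0.695 FPKM (log2 fold -3.08, limma adjusted p = 0.00453). Clca3b, a chloride channel regulator outside the lists, fell from 208 ± 23.5 to 26.4 ± 7.82 FPKM (log2 fold -2.95, limma adjusted p = 0.00453). This list did not pass without Control replicate 2 (median 0.30, camera adjusted p = 0.168), without AIR replicate 1 (0.14, 0.159) or with the series-table values of Control replicate 2 (0.45, 0.0998). Genes of NRF2 and oxidative stress rose in 7 and fell in 1 of 21, as many when adjusted over the list alone. Over the NRF2 targets the median log2 fold was 0.48 (camera adjusted p = 0.000122; adjusted p = 0.549 with an estimated correlation). Gsta3, a glutathione transferase, rose (log2 fold 2.78, SE 0.17, limma adjusted p = 0.00405), while Gstm3, another, fell (log2 fold -1.16, limma adjusted p = 0.0296). After GC correction Gstm3 did not pass (log2 fold -0.84, SE 0.29, limma adjusted p = 0.0741). Goblet cell genes did not stand apart as a list (2 of 19 lower, as many when adjusted over the list alone, camera adjusted p = 0.901). Muc2, the main intestinal mucin, was at 24.3 ± 7.32 FPKM in AIR and 39.4 ± 5.38 in Control (log2 fold -0.70, limma adjusted p = 0.0565). It passed with the series-table values of Control replicate 2 (log2 fold -0.59, limma adjusted p = 0.0244), but not with GC correction as well (limma adjusted p = 0.307). DNA repair genes had 12 lower and 1 higher of 30, as many when adjusted over the list alone. They did not pass as a list (camera adjusted p = 0.0614, or 0.684 with an estimated correlation). At the preset correlation they passed after GC correction (median log2 fold -0.29, camera adjusted p = 0.000196) and with median-ratio scaling (-0.30, 0.0371). In the main values the camera test also left out cholesterol synthesis (adjusted p = 0.0751, or 0.0366 after GC correction), YAP and TEAD targets (0.139) and cell death machinery (0.194). It did not call pancreatic acinar cells (0.316), TLR4 pathway components (0.540), BMP signalling (0.619) and endothelium (0.715). Its adjusted p lay between 0.843 and 0.913 for enteroendocrine cells, macrophages and dendritic cells, NF-kB targets, nuclear oxidative phosphorylation, mucosal defence and the unfolded protein response.

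By limma with Benjamini-Hochberg adjustment, 2786 of 10415 tested genes passed in AIR against Control, 838 higher and 1948 lower, and 4364 had an unadjusted p under 0.05. The median log2 fold of all genes was -0.131, and with median-ratio scaling, which set it to 0, the split was 1165 higher and 1182 lower. The count was 4329 without Control replicate 2, 124 without AIR replicate 1 and 933 without AIR replicate 3. It was 1438 and 1436 without AIR + MPLA replicates 1 and 3, which add only to the shared estimate of spread. With the series-table values of Control replicate 2 it was 6490, 2761 of them shared. Of 68 named genes that passed, 15 passed without AIR replicate 1, among them Lgr5, Ly6a, S100a6, Cd74, Mcm2, Axin2 and Gsta3. Of the same 68, 50 passed without AIR replicate 3, 57 and 54 without Control replicates 2 and 3, and 54 and 55 without AIR + MPLA replicates 1 and 3.

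AIR + MPLA was compared with AIR to find how MPLA changed the irradiated crypt. The goblet cell mucus genes Fcgbp and Muc2 and markers of stem cells were higher, and several p53 targets lower, with MPLA. Fcgbp, a mucus protein of goblet cells (gene ID 215384, chromosome 7, 28071236 to 28120864), was at 518 ± 11.9 FPKM in AIR + MPLA and 147 ± 25.3 in AIR (SD, n = 2; log2 fold 1.82, SE 0.21, limma adjusted p = 0.0153). Muc2 (gene ID 17831, chromosome 7, 141690340 to 141754691) was at 59.5 ± 1.03 FPKM and 24.3 ± 7.32 (log2 fold 1.29, SE 0.22, limma adjusted p = 0.0166). Stem cell markers rose in 10 of 21 tested members, and the other 11 did not pass. Ccng1 fell from 67.4 ± 2.38 to 22.6 ± 2.92 FPKM (SD, n = 2; log2 fold -1.54, SE 0.24, limma adjusted p = 0.0153). The Control mean was 18.3 FPKM, from 22.7 in replicate 2 (9.28 in the series table) and 13.9 in replicate 3. After GC correction the log2 fold of Ccng1 was 1.46 in AIR against Control and -0.86 here, so the fall was smaller than the rise.

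When adjusted over the list alone, 11 stem cell markers were higher with MPLA. Over all tested members of the list the median log2 fold was 0.72 (camera adjusted p = 0.0271; adjusted p = 0.952 with an estimated correlation). Sox9, a transcription factor of the crypt base (log2 fold 0.97, limma adjusted p = 0.0167), and Ephb2, a receptor that positions crypt cells (log2 fold 0.92, SE 0.15, limma adjusted p = 0.0154; after GC correction log2 fold 0.44, SE 0.13, adjusted p = 0.0670), rose. Lgr5 did not pass, at 0.791 ± 0.303 FPKM in AIR + MPLA and 0.267 ± 0.00240 in AIR (log2 fold 0.49, limma adjusted p = 0.0767; adjusted p = 0.0224 with the series-table values of Control replicate 2, at the same fold). Nor did Olfm4, at 251 ± 73.0 FPKM and 168 ± 109 (log2 fold 0.72, limma adjusted p = 0.257). Targets of p53 fell in 8 of 30 tested members, as many when adjusted over the list alone. Over the p53 targets the median log2 fold was -0.16 (camera adjusted p = 0.0271; adjusted p = 0.952 with an estimated correlation). They included Trp53inp1, a p53-induced nuclear protein (log2 fold -1.58, limma adjusted p = 0.0188), whose log2 fold after GC correction was -0.68 (limma adjusted p = 0.0456). Pmaip1, the pro-apoptotic factor Noxa, fell as well (log2 fold -2.43, SE 0.56, limma adjusted p = 0.0254; after GC correction log2 fold -1.89, SE 0.58, adjusted p = 0.0796). Cdkn1a was at 114 ± 20.9 FPKM and 82.0 ± 29.2 and did not pass (log2 fold 0.51, limma adjusted p = 0.299). Transcripts of regenerative and fetal-like epithelium fell in 3 of 20 members, 1 when adjusted over the list alone. Over the regenerative transcripts the median log2 fold was -0.51 (camera adjusted p = 0.0273; adjusted p = 0.952 with an estimated correlation). Among single genes Nt5e fell from 66.2 ± 48.2 to 6.48 ± 4.22 FPKM (SD, n = 2; log2 fold -3.08, SE 0.56, limma adjusted p = 0.0176). Clu was at 4.999 ± 1.24 FPKM and 5.30 ± 4.65 and did not pass (log2 fold 0.14, limma adjusted p = 0.832; log2 fold -0.34 after GC correction). T cell and intraepithelial lymphocyte markers passed as a list with 1 of 11 members lower, none when adjusted over the list alone, in limma. Over the T cell markers the median log2 fold was -0.30 (camera adjusted p = 0.0303; adjusted p = 0.952 with an estimated correlation).

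DNA replication genes were higher in 17 and lower in 2 of 40 tested members, or 23 and 2 when adjusted over the list alone, and did not pass as a list. Over the replication genes the median log2 fold was 0.51 (camera adjusted p = 0.0633). After GC correction the median was 0.28 and the camera test passed (adjusted p = 0.00259; adjusted p = 0.834 with an estimated correlation). Mcm2 rose from 8.17 ± 0.114 to 18.1 ± 0.655 FPKM (SD, n = 2; log2 fold 1.06, SE 0.14, limma adjusted p = 0.0153; log2 fold 0.58 after GC correction). Ccne2, which encodes cyclin E2, fell (log2 fold -1.19, limma adjusted p = 0.0173) but not after GC correction (log2 fold -0.03, limma adjusted p = 0.919). Mitosis genes were higher in 11 and lower in 3 of 40, as many when adjusted over the list alone (camera adjusted p = 0.911). Plk1, a kinase of mitotic entry, rose from 11.5 ± 0.631 to 31.1 ± 1.69 FPKM (log2 fold 1.37, SE 0.18, limma adjusted p = 0.0153). Mki67 did not pass (log2 fold -0.41, limma adjusted p = 0.421; adjusted p = 0.0263 with the series-table values, at the same fold). Cholesterol synthesis genes were higher in 11 and lower in 1 of 21, as many when adjusted over the list alone. Over the cholesterol synthesis genes the median log2 fold was 0.69 (camera adjusted p = 0.0789). After GC correction it was 0.48 (camera adjusted p = 0.00120; adjusted p = 0.834 with an estimated correlation). Dhcr7, the enzyme of the last step to cholesterol, rose from 8.28 ± 0.823 to 25.3 ± 1.495 FPKM (SD, n = 2; log2 fold 1.51, SE 0.16, limma adjusted p = 0.0153). Idi1, isopentenyl diphosphate isomerase, fell (log2 fold -1.03, SE 0.22, limma adjusted p = 0.0208; after GC correction log2 fold -0.46, SE 0.12, adjusted p = 0.0523). Goblet cell genes rose in 5 of 19, as many when adjusted over the list alone. They did not pass as a list (median log2 fold 0.39, camera adjusted p = 0.0845), and the median was 0.15 after GC correction (0.331). Clca3b (log2 fold 1.78, limma adjusted p = 0.0153), Syna, a syncytin (log2 fold 1.71, limma adjusted p = 0.0153), Reep6 (log2 fold 1.70, limma adjusted p = 0.0153) and Gstm3 (log2 fold 1.65, limma adjusted p = 0.0167) were among the largest rises. Clec2e, a C-type lectin, was among the largest falls (log2 fold -2.20, limma adjusted p = 0.0153). So were Clca4a, a chloride channel regulator (log2 fold -2.73, SE 0.71, limma adjusted p = 0.0329; after GC correction log2 fold -2.36, SE 0.82, adjusted p = 0.105), and Slc28a2, a nucleoside transporter (log2 fold -2.39, SE 0.72, limma adjusted p = 0.0460; after GC correction log2 fold -2.35, SE 0.79, adjusted p = 0.0960).

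Genes of the receptor pathway that MPLA engages moved both ways, with 3 higher and 2 lower of 21 tested, or 1 and 2 when adjusted over the list alone (camera adjusted p = 0.526). Ticam1, the adaptor TRIF (log2 fold 1.01, limma adjusted p = 0.0181; after GC correction log2 fold 0.52, adjusted p = 0.0484), and Myd88, the adaptor of most Toll-like receptors (log2 fold 0.61, SE 0.18, limma adjusted p = 0.0448; after GC correction log2 fold 0.19, SE 0.14, adjusted p = 0.391), rose. Ly96, the MD-2 coreceptor, fell from 7.41 ± 1.08 to 3.803 ± 0.133 FPKM (log2 fold -0.80, limma adjusted p = 0.0251). Its direction turned after GC correction (log2 fold 0.08, limma adjusted p = 0.735). NF-kB and inflammatory targets had 4 higher of 16, 3 when adjusted over the list alone (camera adjusted p = 0.675). Tnf did not pass (log2 fold -0.05, limma adjusted p = 0.896). Type I interferon response genes passed in 1 of 30 members, none when adjusted over the list alone, by limma (camera adjusted p = 0.296). Isg15 did not pass (log2 fold -0.27, limma adjusted p = 0.778). H2-Ab1, a class II beta chain, fell from 15.1 ± 5.04 to 5.48 ± 1.56 FPKM (SD, n = 2; log2 fold -1.30, SE 0.34, limma adjusted p = 0.0331). Its list of interferon gamma response and antigen presentation had 4 lower and 1 higher of 26, or 1 and 1 when adjusted over the list alone (camera adjusted p = 0.296). After GC correction that list passed camera at the preset correlation (median log2 fold -0.40, adjusted p = 0.022). Among cell death genes Casp4, an inflammatory caspase, fell from 15.4 ± 0.327 to 4.52 ± 0.691 FPKM (log2 fold -1.58, SE 0.20, limma adjusted p = 0.0153). The list had 4 lower and 2 higher of 23, as many when adjusted over the list alone (camera adjusted p = 0.433). Fabp2 fell from 2308 ± 74.9 to 865 ± 107 FPKM (log2 fold -1.42, SE 0.24, limma adjusted p = 0.0158). The enterocyte list had 5 lower and 4 higher of 30, as many when adjusted over the list alone (camera adjusted p = 0.365). Paneth cell genes passed in none of 24 members by limma, over all genes or adjusted over the list alone. Over the Paneth cell genes the median log2 fold was 0.56 (camera adjusted p = 0.433). Camera called this list with the replicate number as a block (adjusted p = 0.0298). It also did so with GC correction and the series-table values together (median log2 fold 0.47, camera adjusted p = 0.00648), but not with GC correction alone (0.155). Lyz1 was at 2247 ± 464 FPKM and 1448 ± 152 (log2 fold 0.62, limma adjusted p = 0.360; adjusted p = 0.0352 with the series-table values, at the same fold). For the other 14 lists the camera adjusted p lay between 0.111 (Notch signalling, and YAP and TEAD targets) and 0.926 (endothelium). After GC correction YAP and TEAD targets passed (median log2 fold -0.54, camera adjusted p = 0.0428).

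**Figure D2:**
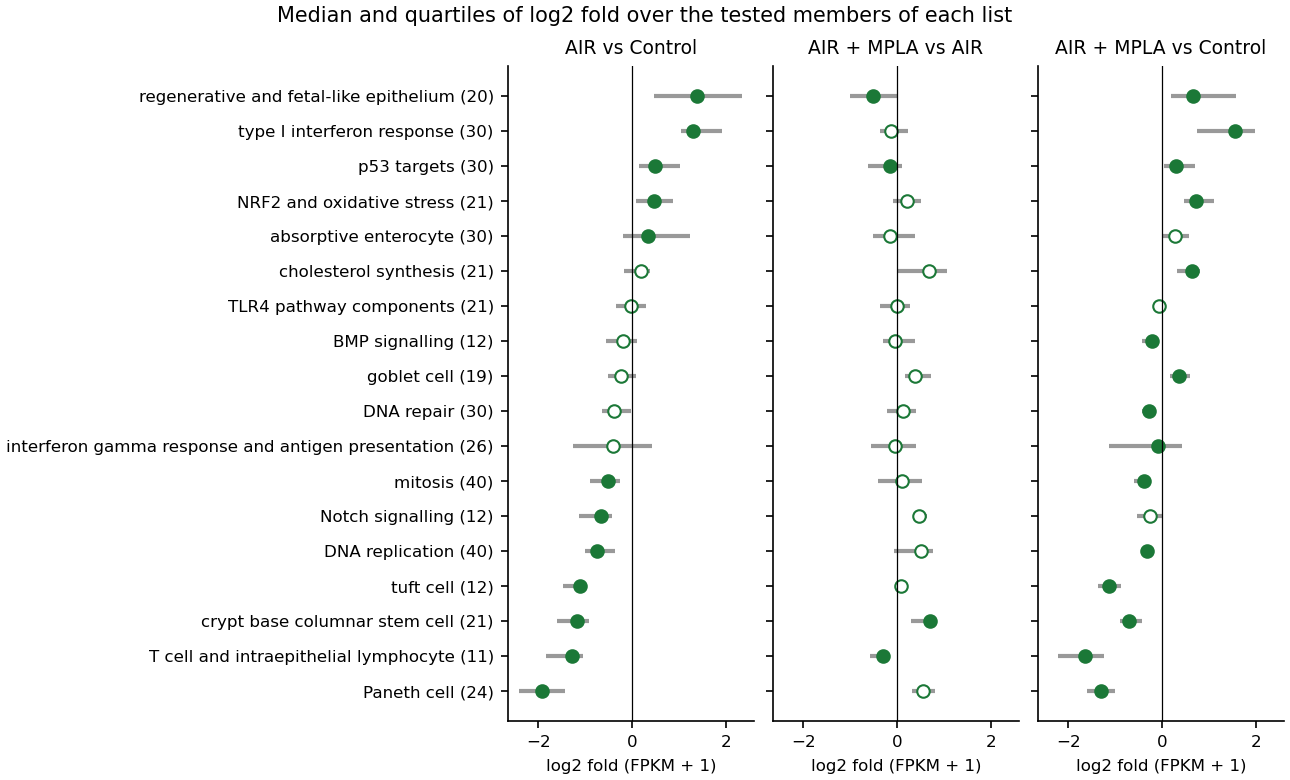
Median log2 fold (point) and quartiles (line) of the tested members of 18 fixed gene lists in the 3 comparisons, on the log2(FPKM + 1) scale, with filled points for a camera adjusted p under 0.05 at the preset correlation. In AIR against Control the medians ran from -1.92 for Paneth cells to 1.39 for regenerative epithelium. No filled point stayed filled with an estimated correlation, a test limited to 3 residual degrees of freedom.

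By limma with Benjamini-Hochberg adjustment, 3060 of 10415 genes passed in AIR + MPLA against AIR, 2029 higher and 1031 lower, with 4720 at an unadjusted p under 0.05. The median log2 fold of all genes was 0.146, and median-ratio scaling gave 1341 higher and 1365 lower. Leaving out any of the 4 libraries compared left 0 genes past the limma threshold. At an unadjusted p under 0.05 there were 3665 and 3365 without AIR replicates 1 and 3, and 3089 and 2457 without AIR + MPLA replicates 1 and 3. Without Control replicates 2 and 3, 4893 and 4890 genes passed. Without AIR replicate 1 the fall of the regenerative list was gone, with a median log2 fold of -0.02 (camera adjusted p = 0.512). In that setting the p53 targets had a median of -0.06 (0.139) and stem cell markers of 0.49 (0.0962). Without AIR + MPLA replicate 1 the medians were -0.16 for p53 targets (camera adjusted p = 0.0885), 0.42 for stem cell markers (0.0995) and -0.45 for regenerative transcripts (0.0995). T cell markers were then at -0.16 (0.251), and at -0.29 (0.0575) without AIR replicate 3. With the series-table values of Control replicate 2, which enter the shared estimate of spread, 5724 genes passed and the 4 lists had a camera adjusted p of 0.0753.

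Fold changes in this comparison followed the GC content of the transcripts. Spearman's rho across 10057 genes was 0.65. The median log2 fold was -0.61 in the fifth of genes with the lowest GC content (up to 44.3%) and 0.49 in the fifth with the highest (over 55.8%). After the trend was removed from each library, 1180 genes passed, 642 higher and 538 lower, of which 818 were among the 3060, and 97 of the 3060 changed sign. Of 54 named genes that passed, 27 passed after this correction, among them Fcgbp, Muc2, Clca3b, Nt5e, Ccng1, Trp53inp1, Mcm2, Plk1, Sox9, Casp4, Fabp2, H2-Ab1, Ticam1 and Dhcr7. The log2 fold of Fcgbp was then 1.33 (limma adjusted p = 0.0268), that of Ccng1 -0.86 (0.0268) and that of Plk1 0.88 (0.0268). The stem cell and p53 lists had medians of 0.46 and -0.31 and both a camera adjusted p of 0.00120 (adjusted p = 0.834 with an estimated correlation). The regenerative list did not pass (median -0.46, 0.0896). In AIR against Control rho was -0.45, and 2515 genes passed after correction, 1248 higher and 1267 lower, with 1706 among the 2786. In AIR + MPLA against Control rho was 0.40. With the series-table values of Control replicate 2 rho was -0.58 for AIR and -0.06 for AIR + MPLA against Control.

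**Figure D3:**
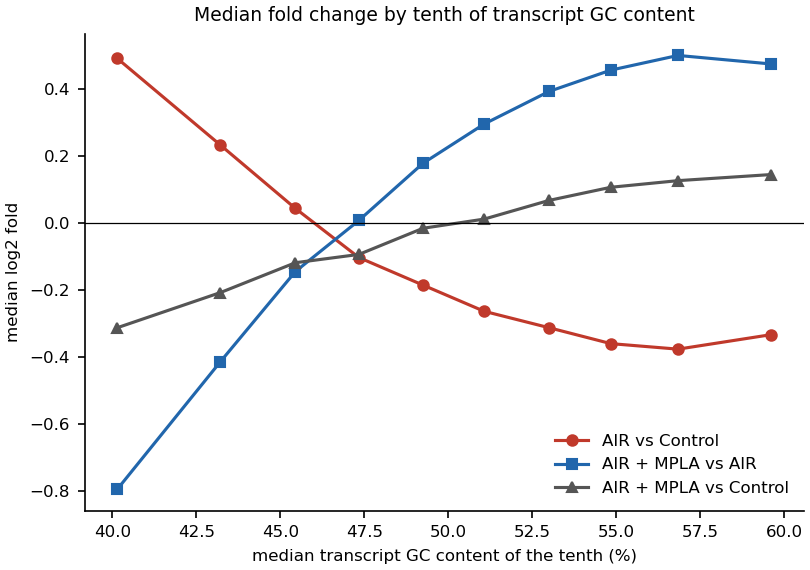
Median log2 fold of the tested genes in 10 bins of equal gene number by transcript GC content (x axis, percent) for the 3 comparisons. The AIR + MPLA against AIR line climbs with GC content while the AIR against Control line falls, with Spearman's rho of 0.65 and -0.45 across genes.

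AIR + MPLA was compared with Control to find which differences from unirradiated crypts were present with MPLA. MHC class II genes were the largest falls. Cd74 was at 11.2 ± 0.611 FPKM in AIR + MPLA and 171 ± 71.0 in Control (SD, n = 2; log2 fold -3.75, SE 0.28, limma adjusted p = 0.00987). H2-Ab1 was at 5.48 ± 1.56 FPKM and 80.5 ± 32.7 (log2 fold -3.61, limma adjusted p = 0.0154), and H2-Eb1 at 2.27 ± 0.113 FPKM and 33.4 ± 13.2 (log2 fold -3.34, limma adjusted p = 0.00987). Lgr5 stayed lower, at 0.791 ± 0.303 FPKM against 3.89 ± 0.470 (log2 fold -1.46, SE 0.18, limma adjusted p = 0.0204). The largest rises were those of Ly6a, at 74.99 ± 41.2 FPKM against 2.96 ± 1.51 (log2 fold 4.20, SE 0.55, limma adjusted p = 0.0228), then S100a6 (log2 fold 3.81, limma adjusted p = 0.0157) and Alb, the albumin gene (log2 fold 3.67, limma adjusted p = 0.0257). Isg15 (log2 fold 2.21, limma adjusted p = 0.193), Clu (log2 fold 2.44, limma adjusted p = 0.0677) and Olfm4 (log2 fold -1.35, limma adjusted p = 0.221) did not pass. Cdkn1a (log2 fold 1.18, limma adjusted p = 0.186) and Lyz1 (log2 fold -1.20, limma adjusted p = 0.306; 0.00108 with the series-table values of Control replicate 2) did not either. Nor did Muc2, Mki67 and Tnf (limma adjusted p = 0.262, 0.306 and 0.966).

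T cell and intraepithelial lymphocyte markers were lower in 10 of 11 tested members, 11 when adjusted over the list alone. Over the T cell markers the median log2 fold was -1.64 (camera adjusted p = 1.02e-15; adjusted p = 0.357 with an estimated correlation). Tuft cell markers were lower in 7 of 12, 11 when adjusted over the list alone. Over the tuft cell markers the median log2 fold was -1.14 (camera adjusted p = 8.46e-13; adjusted p = 0.124 with an estimated correlation). Type I interferon response genes passed in 1 of 30 members, but 24 were higher when adjusted over the list alone. Over the type I interferon genes the median log2 fold was 1.56 (camera adjusted p = 4.54e-16; adjusted p = 0.410 with an estimated correlation). Likewise NRF2 targets had 3 of 21 higher, 12 when adjusted over the list alone. Over the NRF2 targets the median log2 fold was 0.73 (camera adjusted p = 2.74e-11; adjusted p = 0.357 with an estimated correlation). Cholesterol synthesis genes had 2 of 21 higher, 13 when adjusted over the list alone. Over the cholesterol synthesis genes the median log2 fold was 0.65 (camera adjusted p = 3.42e-10; adjusted p = 0.357 with an estimated correlation). Stem cell markers had 1 of 21 lower, 13 when adjusted over the list alone. Over the stem cell markers the median log2 fold was -0.70 (camera adjusted p = 1.61e-09; adjusted p = 0.357 with an estimated correlation). Regenerative transcripts had 2 of 20 higher, 8 when adjusted over the list alone. Over the regenerative transcripts the median log2 fold was 0.67 (camera adjusted p = 3.39e-06; adjusted p = 0.424 with an estimated correlation). Targets of p53 had 1 higher and 1 lower of 30, or 8 and 1 when adjusted over the list alone. Over the p53 targets the median log2 fold was 0.31 (camera adjusted p = 0.000242; adjusted p = 0.406 with an estimated correlation).

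No single member passed by limma over all genes in the lists of Paneth cells, mitosis, DNA replication, DNA repair, goblet cells and BMP signalling, which camera called. For Paneth cells 7 of 24 members were lower when adjusted over the list alone. Over the Paneth cell genes the median log2 fold was -1.30 (camera adjusted p = 7.78e-08; adjusted p = 0.549 with an estimated correlation). The size of this fall rested on the Control libraries. Without Control replicate 3 the median was -0.35 and the list did not pass (camera adjusted p = 0.0834), and with the series-table values of Control replicate 2 it was -2.44. Medians were -0.38 for mitosis (camera adjusted p = 5.13e-10; adjusted p = 0.357 with an estimated correlation), -0.32 for DNA replication (2.31e-07; adjusted p = 0.406 with an estimated correlation) and -0.27 for DNA repair (8.47e-05; adjusted p = 0.410 with an estimated correlation). Goblet cell genes had a median of 0.36 (camera adjusted p = 0.000477; adjusted p = 0.549 with an estimated correlation) but did not pass without Control replicate 2 (median 0.21, 0.144) or with its series-table values (median 0.08, 0.340). BMP signalling (median -0.20, 0.0348; adjusted p = 0.366 with an estimated correlation) did not pass without Control replicate 3 (median -0.27, 0.155). Interferon gamma and antigen presentation genes had 6 of 26 lower, 8 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.00998; adjusted p = 0.761 with an estimated correlation). Their median log2 fold was -0.10, and the list did not pass without Control replicate 3 (median 0.04, 0.232) or AIR + MPLA replicate 1 (median 0.10, 0.272). For the other 14 lists the camera adjusted p lay between 0.0923 (absorptive enterocyte) and 0.997 (TLR4 pathway components). Among these, 4 passed camera with the series-table values of Control replicate 2, namely pancreatic acinar cells (0.000132), Notch signalling (0.0185), and macrophages and mucosal defence (both 0.0236). None of the 4 passed with an estimated correlation (smallest adjusted p = 0.293). In all, camera called 20 lists with the series-table values. Lists with fewer than 3 tested members in the main values were among them and are not described here.

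By limma with Benjamini-Hochberg adjustment, 154 of 10415 genes passed in AIR + MPLA against Control, 67 higher and 87 lower, and 1674 had an unadjusted p under 0.05. The count was 238 and 1645 without Control replicates 2 and 3, 45 and 41 without AIR replicates 1 and 3, and 13 and 29 without AIR + MPLA replicates 1 and 3. It was 1108 with the series-table values of Control replicate 2 (149 of the 154 shared) and 294 after GC correction (148 shared). Lgr5 did not pass when any of the 4 irradiated libraries was left out. Ly6a and Alb did not without either Control library or AIR + MPLA replicate 3, nor S100a6 without Control replicate 2 or Alb without AIR + MPLA replicate 1. Cd74, H2-Ab1 and H2-Eb1 passed without each library in turn.

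Across 10415 genes the log2 fold of AIR + MPLA against AIR ran against that of AIR against Control, with Pearson's r of -0.74 and a slope of -0.69. Both comparisons use the AIR libraries. In 100 simulations with no difference between AIR + MPLA and AIR, this sharing gave r between -0.187 and -0.132 (mean -0.163). Noise was drawn independently for each gene there, so shifts common to many genes, such as the GC trend, are not in that range. The covariance was -0.277 against a simulated -0.0236, a difference of -0.253. Of the 2786 genes that passed in AIR against Control, 2647 (95.01%) had the opposite sign in AIR + MPLA against AIR, compared with 59.0% in the simulations. Genes past both thresholds comprised 1272 lower and then higher, such as Mcm2, Hes1 and Dhcr7, and 480 higher and then lower, such as Ccng1, Nt5e and Fabp2. Independent lists of these sizes would share 380 and 83.0. These lists are not independent, since the AIR libraries enter both comparisons with opposite sign. That alone favours opposite directions, so the counts for independent lists do not measure the excess. Another 7 genes were lower and lower, H2-Ab1 among them, and 5 higher and higher, against 193 and 163 for independent lists. The balance of the opposite courses depended on the setting. Median-ratio scaling gave 702 genes lower and then higher and 716 higher and then lower, and GC correction 444 and 379. After GC correction r was -0.68 and 91.4% of called genes had the opposite sign. The rise of Hes1 in AIR + MPLA against AIR did not pass after this correction (log2 fold 0.51, SE 0.17, limma adjusted p = 0.0893). With the AIR libraries split so that none was shared, r was -0.52 (covariance -0.222) with AIR replicate 1 set against Control and replicate 3 against AIR + MPLA, and -0.72 (covariance -0.273) the other way round. In these splits r was -0.40 and -0.61 after GC correction. A technical shift common to both AIR libraries would remain in either split and also give a negative r. The splits therefore cannot exclude it.

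**Figure D4:**
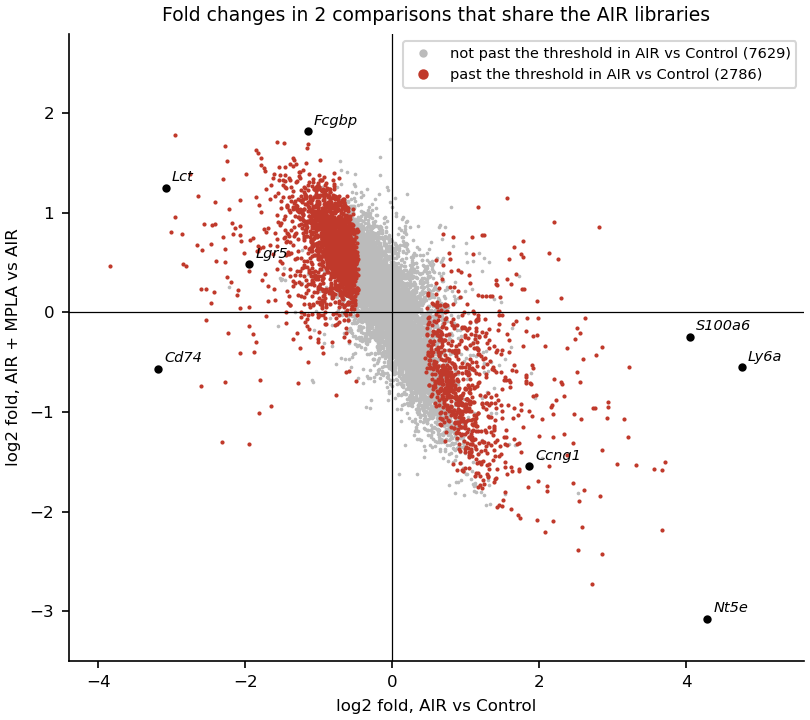
Log2 fold of AIR + MPLA against AIR (y axis) and of AIR against Control (x axis) for 10415 genes on the log2(FPKM + 1) scale, with the 2786 genes past the threshold in AIR against Control in red and named genes in black. Ccng1 and Nt5e lie at the lower right, Fcgbp and Lct at the upper left, and Cd74 at the lower left; r was -0.74, against a mean of -0.163 simulated from the shared AIR libraries with independent noise per gene.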

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

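The test of a different scaling was chosen after its result was seen; the tests of an irradiated library and of GC and length bias were written before theirs. A column of the series table carries the name of Control replicate 2 and is in none of the main comparisons, which take that library from its own file. Its highest value was that of Defa24, a Paneth cell alpha-defensin, at 37711.1 FPKM, against 10144.1 in the own file of Control replicate 2, 29538.8 in Control replicate 3 and at most 7617.2 in the irradiated libraries. Across genes, Pearson's r was 0.997 between this column and Control replicate 3, 0.972 between the own file and Control replicate 3, and 0.966 between both versions of Control replicate 2. With groups of 2 libraries, no test for a library far from its group applied.

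Why Control replicate 2 has other values in its own file than in the series table was weighed on these tables. Against 1 library scaled differently, the log2 ratio of both versions had an SD over genes of 0.50, while that between Control replicates 2 and 3 of the series table was 0.142. Against GC and length bias as the whole cause, the SD of the difference was 0.37 after both trends were removed (0.138 between the series-table replicates), and 24 Paneth cell genes had a median difference of -2.07 before and -1.88 after removal. Whether the own file holds an irradiated library was not settled by position on a scale from 0 at the series-table controls to 1 at AIR. The median of 5013 genes was 0.25 (quartiles -0.059 to 0.59), that of the 826 with over 2-fold change was 0.19, and the AIR + MPLA libraries lay at 0.33 and 0.33. Single markers, picked after their values were seen, went both ways. Axin2, Alox5ap and Cd3e were at 13.3, 4.76 and 2.45 FPKM in the own file, against at most 8.91, 0.835 and 0.569 in the irradiated libraries. Cd74 was at 121 FPKM in the own file, against at most 18.9. Clu, Anxa10 and Alb were at 0.066, 0.042 and 0.107 FPKM there, against at least 2.01, 3.735 and 3.305 in the irradiated libraries. Of the genes named here only Ang4, a Paneth cell gene, went the other way. It was at 205 FPKM in the own file, within the 181 to 298 of the irradiated libraries. Another control sample under the same name stays open as well and was not tested.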

How the results depend on the processing

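The series-table values of Control replicate 2, the GC, GC and length, and block with GC corrections, the 5 FPKM filter and the split of the AIR libraries were chosen after seeing the data; the other alternatives were planned. The planned count-based tests and the CPM filter were not run, because the values are FPKM. For the named genes, settings other than leaving out a library gave 1468 values with the same direction and side of the threshold, 241 no longer past it, 14 newly past it and 16 of opposite sign; leaving out 1 library gave 516, 359, 8 and 11. The called lists gave 333 the same and 76 no longer past it, or 171 and 15 with 1 library left out. The opposite course of the comparisons that share the AIR libraries held its direction in all 16 settings tried, with r from -0.57 without Control replicate 3 to -0.81 with the series-table values, and at -0.52 and -0.72 with the AIR libraries split between the comparisons. Depth in reads is unknown, so no limit for low genes can be given, and 3 residual degrees of freedom limit the spread that can be estimated.

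Counts of genes past the limma threshold in AIR against Control (2786), AIR + MPLA against AIR (3060) and AIR + MPLA against Control (154) moved by over 1.5 times in these settings. With 1 library left out they ranged from 124 to 4329, from 0 to 4893 and from 13 to 1645; a group then has 1 library. With only the 4 libraries compared, they were 1427, 4899 and 43. Without haemoglobin and defensin genes in the totals they were 1426 in AIR + MPLA against AIR and 89 in AIR + MPLA against Control, and without a filter, when 16529 genes are tested, 1181 and 73. The filter of 5 FPKM gave 57 in AIR + MPLA against Control, of 7355 genes tested. With the series-table values they were 6490, 5724 and 1108, and with GC correction as well 5041 and 1273 in the comparisons with Control. GC correction alone gave 1180 and 294 in both comparisons of AIR + MPLA, and GC and length correction 1355 and 325. For these counts the cause was not tested.

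Camera with an estimated correlation called 0 lists in each comparison, against 12, 4 and 15; the smallest adjusted p was 0.365, 0.952 and 0.124. This form of camera has only the 3 residual degrees of freedom, so the loss cannot be credited to correlated members alone. Tuft cell markers had an estimated correlation of -0.078. Their unadjusted camera p in AIR against Control still went from 3.40e-07 to 0.0126. Fry called 0 in AIR + MPLA against AIR and 3 in AIR + MPLA against Control. In AIR + MPLA against AIR camera called 2 lists with median-ratio and 2 with upper-quartile scaling, 8 without a filter, 0 with the series-table values, 7 with GC correction, 8 with GC correction and the series-table values, 9 with GC and length correction, 0 with the 5 FPKM filter, and 0 to 11 with 1 library left out. For the other settings the cause was not tested.

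Signs turned for genes that had not passed, except Ly96. Mki67 in AIR against Control (main log2 fold -0.50) was at 0.12 with the series-table values, 0.049 with GC correction as well, and -1.15 to 0.14 with 1 library left out. Tnf in AIR against Control (main 0.07) was at -0.26 with the series-table values and -0.21 to 0.35 with 1 library left out, and in AIR + MPLA against AIR (main -0.05) at -0.26 to 0.17. In AIR + MPLA against Control Tnf (main 0.02) was at -0.021 without haemoglobin and defensin genes, -0.31 with the series-table values, -0.030 with GC correction, -0.31 with both, -0.065 with GC and length correction, and -0.25 to 0.30 with 1 library left out. Clu in AIR + MPLA against AIR (main 0.14) was at -0.34 with GC correction, -0.34 with the series-table values as well, -0.30 with GC and length correction, -0.33 with the replicate block and GC correction, and -0.69 to 0.98 with 1 library left out; Isg15 (main -0.27) was at -0.95 to 0.41. Ly96 in AIR + MPLA against AIR (main -0.80, limma adjusted p = 0.0251) was at 0.078, 0.086, 0.33 and 0.075 in the 4 settings named for Clu. Ly96 has a GC content of 38.9%, and the correction removes the trend with it.

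AIR and AIR + MPLA share the replicate numbers 1 and 3. The correlation of the deviations of same-numbered libraries was -0.33, and with 2 pairs they share only a number. With this number as a replicate block, 3562 genes passed by limma in AIR + MPLA against AIR (2866 of the 3060), and camera called 5 lists, that of Paneth cells among them. With the replicate block and GC correction 0 genes passed by limma, 3459 had an unadjusted p under 0.05, and camera called 10 lists. No paired analysis was possible because the groups share fewer than 2 numbers with Control, namely the number 3 alone, for the comparisons with Control.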

Other observations

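The gene terms named in this part were picked after their results were seen, and all tests of explanations here were chosen after the result was seen except that on zinc finger genes. Among Gene Ontology and pathway terms that passed camera at the preset correlation in the main values and with both GC-corrected versions, 1 moved in both irradiated comparisons. Genes of aminoacyl-tRNA ligase activity, which load tRNAs with amino acids, were lower in AIR than in Control in 14 of 40 members (median log2 fold -0.51, camera adjusted p = 0.0434; 0.0758 with the series-table values of Control replicate 2) and higher in AIR + MPLA than in AIR in 21, with 1 lower (median log2 fold 0.58, camera adjusted p = 0.0330). Nuclear pore constituents were lower in AIR in 10 of 20 members (median log2 fold -0.60, camera adjusted p = 0.0434; 0.365 with the series-table values). Genes annotated to stilbenoid response were higher in AIR in 8 of 12 members (median log2 fold 1.72, camera adjusted p = 0.00120; 0.0632 with the series-table values).

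In AIR + MPLA against Control, 94 terms passed in these 3 versions. Metabolic terms were higher, with few members past the threshold by limma: glutathione metabolism had a median log2 fold of 0.48 over 48 genes (camera adjusted p = 7.54e-08), cytochrome P450 metabolism of xenobiotics 0.46 over 41 (2.68e-07), and PPAR signalling, which controls fatty acid use, 0.36 over 49 (3.48e-06). The intestinal network for IgA production was lower in 5 of 15 genes (median log2 fold -0.63, camera adjusted p = 3.42e-05). Estimated correlations were not computed for terms.

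The course of fold changes in AIR + MPLA against AIR with transcript GC content was weighed first. Against the trend as the whole cause of the calls, 818 of 3060 genes passed in the same direction after its removal; for the other 2242 the median absolute log2 fold went from 0.77 to 0.32 and the median SE from 0.18 to 0.15, so the calls ended because the folds shrank. A GC bias of library preparation unrelated to treatment stays open: the gap between the fifth of genes with the lowest and the fifth with the highest GC content within a group reached 0.70 of that between AIR + MPLA and AIR (0.765 against 1.10), although that group was Control with the doubtful replicate 2, and the ratio was 0.23 without it and 0.083 between the series-table controls. A fall of zinc finger genes as a class under MPLA stays open as a biological hypothesis for part of the trend: 221 Zfp genes had a median log2 fold of -0.44, under the -0.24 (-0.33 to -0.15) of 10000 GC-matched lists. These may act together.

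The fall of MHC class II genes after irradiation was weighed next. Against a GC trend as the whole cause, 6 class II genes (Cd74, H2-Aa, H2-Ab1, H2-Eb1, H2-DMa and H2-DMb1) had a median log2 fold of -1.84 in AIR against Control after GC correction (largest SE 0.40) and -2.19 before it. Fewer macrophages, dendritic cells or B cells in the preparation cannot be told apart from lower class II expression per cell. The median log2 fold of the 7 tested macrophage and dendritic cell markers was -0.497 (from -0.99 to 0.71; camera adjusted p = 0.843). Itgam (log2 fold -0.69, limma adjusted p = 0.0275), Fcer1g (log2 fold -0.99, limma adjusted p = 0.0331) and Tyrobp, named after its value was seen (log2 fold -0.63, limma adjusted p = 0.0453), fell. After GC correction Itgam (log2 fold -0.52, limma adjusted p = 0.0517) and Fcer1g (log2 fold -0.70, limma adjusted p = 0.0668) did not pass. The list median was then -0.19. When adjusted over the list alone, 3 markers were lower and 1 higher. C1qa, also named after its value was seen, was at 1.42 ± 0.762 FPKM in AIR and 0.458 ± 0.285 in Control. Of the markers of B and plasma cells all but Cd79b (log2 fold -0.98, limma adjusted p = 0.0857) and Jchain (log2 fold -0.70, limma adjusted p = 0.157), named after their values were seen, lay below the filter. Both explanations stay open, and which cells carried the class II transcripts was not tested.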
